A study of Mus musculus with 2 samples.

How the data were processed

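Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was used on neural tube of mouse embryos at embryonic day 13.5, pooled from both sexes, with an antibody against histone H3 monomethylated at lysine 4 (H3K4me1). The labels give 2 biological replicates of 1 group, so the p-values below measure peaks, genes or random gene lists within these samples and not a difference between conditions. The labels name a control experiment for the immunoprecipitation; its reads were not analysed here.

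The analysis used 4 peak lists: 1 list per replicate, a list called on both replicates pooled, and a list of replicated peaks. Per the labels and the deposited file descriptions, all 4 lists use the mm10 build, and the replicated list was derived from the pooled list and both replicates' lists. The peak caller, its version, its threshold and the rule for calling a peak replicated are not given in the sources used here. Each peak has a deposited fold enrichment at the peak, a ratio computed by the authors' caller, and a deposited −log10 p and −log10 q. A deposited score per peak was present and was not used in any result. Fold and −log10 values are the authors' own, and served only to describe, rank or filter peaks within a list. The lowest −log10 p lay between 2.0 and 2.02 in all 4 lists and the lowest −log10 q between 0.678 and 0.831, so the lists held weak calls. No read counts were used, so sequencing depth is unknown and no interval on signal could be given; intervals on shares of peaks are exact binomial 95% intervals and cover counting error only.

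Gene positions came from the GENCODE release M21 annotation of GRCm38 and sequence from the GRCm38 reference, the same build as mm10. Peaks on chromosomes 1 to 19 and X were analysed. Peaks on unplaced contigs, 1 in the replicated list, 7 in the pooled list and 3 in each replicate's list, were left out. Positions are 1-based.

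A peak was shared when it overlapped a peak of the other list by at least 50% of either peak's length, and replicate-specific when no base overlapped. Chance overlap came from 100 circular shifts along the sequenced span of each chromosome, and from 10 or 20 shifts for the alternatives. Each peak was assigned by its midpoint to a promoter (within 1 kb of an annotated 5′ end), then exon, intron or intergenic sequence. Single peaks named in the text were assigned by their summit. The start-site profile was taken every 100 bp around the 5′ ends of protein-coding genes with a replicated peak within 5 kb, and its flanks were 1 to 2 kb from the 5′ end.

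For 20 gene lists, the percentage of bases within 50 kb of each 5′ end covered by replicated peaks was computed, and the list median was compared with 10000 random lists of protein-coding genes of the same size, two-sided. The smallest p this test can give is 1e-04. Start-site occupancy (a peak within 5 kb) was tested with two-sided Fisher's exact tests against all other protein-coding genes. The balance between replicates was the log2 ratio of covered bases around the genes of a list, minus that over all protein-coding genes, against random lists. Long stretches were replicated peaks joined across gaps of up to 3 kb, and the 500 with the most bases in peaks were tested for genes of each list within 50 kb. All p-values were adjusted over the lists with the Benjamini-Hochberg procedure at a threshold of 0.05. Genes are not independent, since neighbours share windows, above all in the Hox clusters and among olfactory receptor genes.

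For 20 transcription factor motifs, 500 bp windows around summits more than 2.5 kb from every annotated 5′ end were compared with windows 5 kb away on a random side, outside all pooled peaks, also more than 2.5 kb from 5′ ends and matched on GC content in bins of 2%. Where the chosen side was not usable the other side was taken. The ratio of windows holding the motif on either strand was divided by the median ratio of up to 20 shuffles of the motif's letters with the same number of CG dinucleotides. A motif was called when a two-sided Fisher's exact test passed after Benjamini-Hochberg adjustment and both ratios were above 1. The need for both ratios to lie above 1 was added after the results were seen, since they pointed in opposite directions for 3 motifs; the distance of control windows from 5′ ends, the use of the other side and the CG count of shuffles were set before any motif result was seen.

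Genes were named by a rule: in each list the 3 members with the highest coverage and the 1 with the lowest; 14 genes chosen in advance; the nearest protein-coding gene of the 10 longest stretches; the 5 replicated peaks with the highest fold; and per replicate the 3 strongest peaks absent from the other. Apart from these motif details, the samples' grouping, tests, gene lists, motifs, naming rule and alternatives were fixed before the data were examined. The alternatives were stricter −log10 q or fold minimums, other overlap rules, equal numbers of peaks, joined peaks, each replicate's own list, the pooled list, other windows, other promoter and gap sizes, other annotations and other motif windows. Added after seeing the data were a run on autosomal genes only, the proneural list without its Ebf genes, and a motif call that also had to exceed every letter shuffle.

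The steps were tested on simulated data. Copied and jittered peaks, drawn from a list of 230858 peaks, were found as shared in 100% of cases in every simulated set. A copy that keeps most of its overlap is shared by definition, so this share does not test the overlap rule. Among lists of 20 genes with unchanged coverage, 0.909% of 110 simulated lists were called. With coverage multiplied by 1.5, 2 and 3, 23.3%, 60.0% and 90.0% of 30 lists each were called. Coverage was dealt out to genes at random, so neighbours did not share windows in these simulations. The rate of false calls therefore does not carry over to lists of clustered genes. All 3 motifs planted in 2% of simulated windows were called, and 0 of the 17 others. Simulated peak and control windows had the same base composition and differed only by the planted motifs. The absence of false motif calls therefore does not carry over to genomic sequence. Analyses used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, with the random seed fixed at 11.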

Results

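H3K4me1, a histone mark found at enhancers and around active promoters, was mapped in the embryonic mouse neural tube, the precursor of the brain and spinal cord, at day 13.5. The data were 2 biological replicates of this 1 tissue and stage, so the comparisons are between the replicates and between gene groups, regions and sequence motifs within the tissue. Replicate 1 held 230861 peaks over 140.0 Mb and replicate 2 held 191035 peaks over 110.5 Mb. The list of replicated peaks, which most results below use, held 143623 peaks over 138.7 Mb, or 5.42% of the sequenced genome. Replicated peaks had a median length of 687 bp, reached 31143 bp, and had a median fold enrichment of 3.34 as given by the authors' caller. Values given as mean ± SD are over the replicates' own lists (n = 2).

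The 5 strongest replicated peaks had their summits within genes. The peak with the highest fold enrichment, 14.5, covered positions 35831239 to 35852563 of chromosome 18 (mm10), with its summit in an intron of Cxxc5, which encodes a CXXC zinc finger protein. It was followed by peaks with summits in introns of Ap3d1, a subunit of the AP-3 adaptor complex (chromosome 10, 80739574 to 80741673, fold 13.3), and of Ncor2, a nuclear receptor corepressor (chromosome 5, 125145499 to 125161696, fold 13.1). The peak in an exon of the RNA-binding protein gene Pcbp4 had a fold of 12.9, and that in an intron of Ccdc85c a fold of 12.7.

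The first comparison asked how far the replicates shared their peaks. Of replicate 1's peaks, 56.3% (95% interval 56.1 to 56.5) were shared with replicate 2, and of replicate 2's peaks, 74.7% (74.5 to 74.9) were shared with replicate 1. Circular shifts gave 6.24% and 7.64%, and no more than 7.29% and 9.04% in any of 100 shifts. Strong peaks were shared more than weak ones, with no rise among the weakest peaks of either replicate. In replicate 1, 99.6% of the tenth of peaks with the highest fold were shared and 31.6% of the tenth with the lowest fold; in replicate 2, these shares were 99.8% and 58.1%. Over 129933 pairs of shared peaks, the fold enrichments had a Spearman correlation of 0.515 and a Pearson correlation on the log2 scale of 0.571; these are correlations across peaks, which are not independent replicates. When 50% of both peaks had to overlap, the shared percentages were lower by over 1.5 times in replicate 2, at 37.8% and 45.6% in the replicates.

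Peaks seen in 1 replicate alone were short and weak. In replicate 1, 37.7% of peaks (87128) overlapped no peak of replicate 2, against 18.7% (35717) in replicate 2. In replicate 1 these had a median length of 253 bp and a median fold of 2.67, against 555 bp and 3.46 for the others, and 5.86% against 11.9% lay at promoters. In replicate 2 the medians were 239 bp and 2.64 against 436 bp and 3.20. The strongest peak of replicate 1 without a counterpart, with a fold of 7.23, lay on chromosome 4 at 13093538 to 13093905, 186700 bp from the 5′ end of Triqk. The next were in an exon of Pura, which encodes a nucleic acid binding protein of neurons (chromosome 18, 36288683 to 36288940), and at the promoter of the sarcoglycan gene Sgcb (chromosome 5, 73647694 to 73648298), both with a fold of 6.29. In replicate 2 they lay at the promoter of Sdhaf3 (chromosome 6, 6955370 to 6955660, fold 5.28), in intergenic sequence nearest to Gm31371 (chromosome 8, 20123327 to 20123620, fold 5.28), and in an intron of Sertad2 (chromosome 11, 20552891 to 20553542, fold 5.16).

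The replicated list kept 55.8% of the pooled peaks (143622 of 257591), and every replicated peak was also a row of the pooled list. The peaks kept had a median length of 687 bp and a median fold of 3.34, against 230 bp and 2.32 for those left out. Of the kept peaks, 85.5% matched a peak in both replicates by 50% of either length, 19632 touched a peak of a single replicate, and 565 touched neither. The kept share depended on the threshold: it was 89.8% for pooled peaks with a −log10 q of at least 5 and 99.97% for those with a fold of at least 4.

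H3K4me1 peaks concentrated at promoters and within genes. Of replicated peaks, 11.7% had their midpoint within 1 kb of an annotated 5′ end, 2.96 times the share after circular shifts. Exons held 5.93% (1.45 times), introns 57.3% (1.36 times) and intergenic sequence 25.1% (0.504 times) of midpoints. The replicates' own lists gave 10.1% ± 0.726 at promoters, 58.5% ± 0.0182 in introns and 25.5% ± 0.735 in intergenic sequence. The promoter ratio was 5.05 when the annotation was limited to protein-coding genes.

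Around coding 5′ ends the mark lay on both sides of the start and dipped over it. Of 21728 protein-coding genes, 15233 (70.1%) had a replicated peak within 5 kb of the 5′ end. Among these, a peak covered the 5′ end itself in 24.8% of genes. Coverage rose to 45.8% of genes 500 bp upstream and to 62.0% of genes 1000 bp downstream. In the replicates' own lists the upstream and downstream maxima were 39.7% ± 4.18 and 56.1% ± 2.93, and coverage of the 5′ end was 21.3% ± 3.19. In the flanks from 1 to 2 kb, coverage was 22.6% upstream and 55.0% downstream, with a mean of 38.8%. The ratio of the 5′ end to these flanks was 0.639, and 0.613 ± 0.0518 over the replicates.

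**Figure D1:**
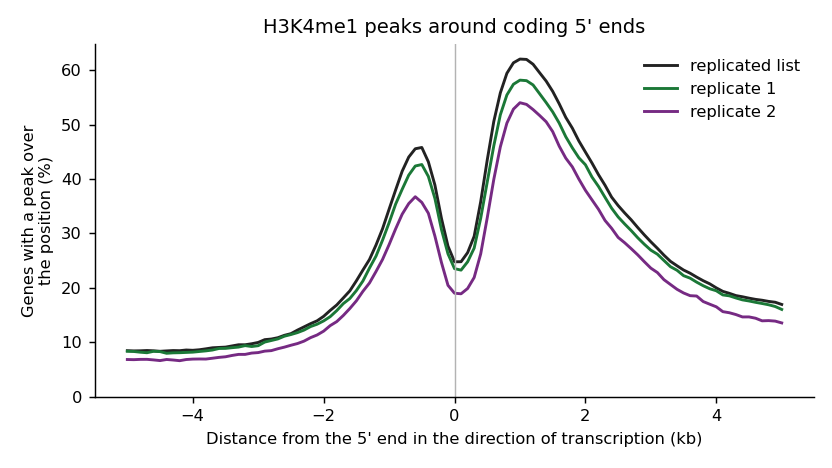
Percentage of protein-coding genes with a peak over each position (y axis) against distance from the annotated 5′ end in kb, in the direction of transcription (x axis), among genes with a peak within 5 kb. Lines stand for the replicated list and each replicate's own list; the replicated list reached 45.8% upstream, 24.8% at the 5′ end and 62.0% downstream.

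Several lists of neural genes, the Hox list and the housekeeping list were surrounded by more marked sequence than random lists of genes. Over all protein-coding genes, a median of 6.15% of the 100 kb around the 5′ end was covered by replicated peaks, and 3633 genes had no covered base. Against random lists (a permutation test), 8 of the 20 lists were higher and 1 was lower. By this permutation test, the highest was the Hox cluster list, with a median of 54.4% (replicates 51.4% ± 1.61; adjusted p = 0.000667), followed by proneural genes at 19.6% (16.04% ± 3.38; adjusted p = 0.0015), neural progenitor genes at 18.9% (16.2% ± 1.83; adjusted p = 0.000667), pan-neuronal genes at 13.5% (12.1% ± 2.10; adjusted p = 0.0123), dorsoventral patterning genes at 13.4% (10.999% ± 1.78; adjusted p = 0.0016), glial lineage genes at 13.0% (10.7% ± 0.839; adjusted p = 0.0202), housekeeping genes at 12.49% (adjusted p = 0.0202) and spinal neuron transcription factor genes at 10.6% (8.80% ± 1.26; adjusted p = 0.0183). The olfactory receptor list, whose genes serve smell in the nose, had a median of 0%, with 911 of its 1092 genes uncovered (permutation test, adjusted p = 0.000667). The smallest unadjusted p that the random lists can give, 1e-04, was reached by the Hox, neural progenitor and olfactory receptor lists.

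**Figure D2:**
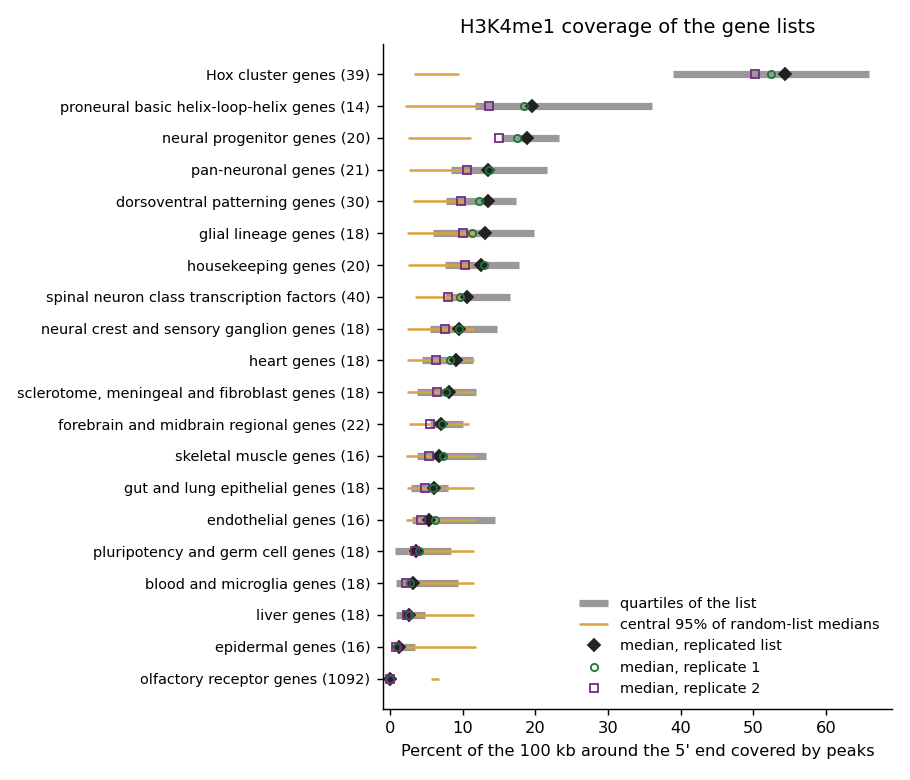
Percentage of the 100 kb around the 5′ end covered by peaks (x axis) for each gene list, with its number of genes (y axis). Diamonds, circles and squares are list medians in the replicated list, replicate 1 and replicate 2, grey bars the quartiles of the list and orange lines the central 95% of medians of random lists; the Hox median of 54.4% lies above all others.

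Among neural progenitor genes, 18 of 20 lay above the median of all genes. Notch1, a receptor that keeps progenitors undifferentiated, had 53.8% of its window covered (replicates 50.1% ± 1.79), Notch2 37.7% (32.5% ± 3.21), and Nes, which encodes the progenitor intermediate filament nestin, 36.7% (33.6% ± 1.42). The progenitor transcription factor genes Sox2 and Pax6 had 23.1% (19.6% ± 2.40) and 20.4% (17.5% ± 1.58). The lowest member was the X-linked gene Sox3, at 2.66%.

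Of 30 dorsoventral patterning genes, 25 lay above the median of all genes. Ptch1, which encodes the Sonic hedgehog receptor, had 34.8% covered (32.2% ± 1.16), and Pax7 and Pax3, transcription factor genes of the dorsal neural tube, had 32.8% (27.4% ± 3.30) and 24.1% (20.9% ± 4.41). Olig2, a gene of motor neuron progenitors, had 13.9% (10.5% ± 1.51), Shh, the ventral signal itself, 8.35% (7.86% ± 1.62), the ventral progenitor gene Nkx2-2 7.39% (6.26% ± 0.655), and the floor plate gene Foxa2 1.97% (1.68% ± 0.713).

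The proneural list holds 11 genes of basic helix-loop-helix factors of neuronal differentiation and 3 Ebf genes, which encode factors of another family. Of these, 13 of 14 lay above the median of all genes, and without the Ebf genes, a choice made after the data were seen, the list median was 14.2% (permutation test, adjusted p = 0.0371). Ebf3 had 50.3% covered (46.3% ± 3.98), Neurod2 39.0% (32.6% ± 3.67) and Ebf1 37.1% (35.1% ± 4.69). Ascl1 and Neurog2 had 14.2% (13.2% ± 1.13) and 11.7% (10.4% ± 1.15), and Neurod4, the lowest, 5.77%. Among 40 transcription factor genes of spinal neuron classes, 33 lay above the median: Lmx1b, a gene of dorsal interneurons, had 49.4% (43.7% ± 4.93), Gbx2 36.5% and Gbx1 34.7%, and Lhx1 22.6% (19.8% ± 2.59). Windows also hold neighbouring genes: long marked stretches in the windows of Gbx2 and Gbx1 had their midpoints in introns of Agap1 and Agap3. The motor neuron genes Mnx1 and Isl1 had 7.64% (6.89% ± 0.454) and 1.85% (2.13% ± 0.127).

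Of the pan-neuronal genes, 17 of 21 lay above the median, led by Rbfox3, which encodes the neuronal nuclear protein NeuN, at 40.8%, the adhesion gene Cntn2 at 34.1% and Ncam1 at 25.5%; the guidance receptor gene Robo1 had 0.858%. Among glial lineage genes, Atp1a2 had 30.9%, Nfia 28.8% and Sox8 25.8%, and the X-linked myelin gene Plp1 0.772%. Among housekeeping genes, Rplp0 had 26.0%, Actb 23.3% and Polr2a 20.1%, and the X-linked Hprt 1.30%. The pan-neuronal, glial and spinal neuron lists no longer passed the test with peaks of at least 4-fold enrichment, the glial and spinal neuron lists did not pass with replicate 1's list alone, and the housekeeping list did not pass against lists matched on gene density.

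Hox genes, which set position along the body axis, formed the most heavily marked group, and 38 of 39 lay above the median of all genes. The HoxA cluster on chromosome 6 (52155590 to 52260880) had 66.4% of its bases in replicated peaks, the HoxD cluster on chromosome 2 (74668310 to 74765142) 57.5%, the HoxC cluster on chromosome 15 (102921103 to 103036852) 54.6% and the HoxB cluster on chromosome 11 (96194316 to 96368256) 51.6%. In the 100 kb windows, Hoxc4 had 83.8% covered (79.3% ± 3.10), Hoxb5 83.05% (78.6% ± 4.52) and Hoxb6 75.5% (71.3% ± 4.77), while Hoxb13, the most posterior gene of HoxB, had 2.63% (2.61% ± 0.552). The 39 genes lie in 4 clusters and share windows, so the p above does not rest on 39 independent genes.

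**Figure D3:**
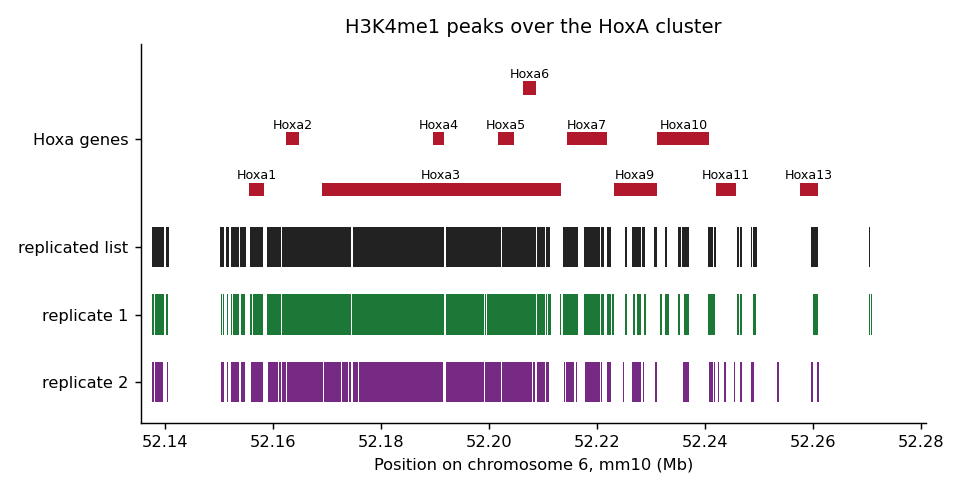
Map of the HoxA cluster on chromosome 6 (x axis, mm10 position in Mb) with Hoxa genes as red bars and peaks of the replicated list and of each replicate as filled blocks (y axis). Peaks cover most of the side from Hoxa1 to Hoxa6 and become sparse towards Hoxa13; 66.4% of the cluster's bases lie in replicated peaks.

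In the 100 kb windows, the forebrain and midbrain list did not pass the test against random lists. Nor did the lists of other tissues, apart from that of olfactory receptor genes. Under other settings, forebrain and midbrain genes passed over gene bodies, sclerotome genes in 10 kb windows and epidermal genes, as lower, with the pooled list. Medians were 6.96% for forebrain and midbrain genes (permutation test, adjusted p = 0.839), 9.43% for neural crest and sensory ganglion genes (0.281), 9.10% for heart genes (0.311), 8.06% for sclerotome, meningeal and fibroblast genes (0.589), 6.70% for skeletal muscle genes (0.894), 6.01% for gut and lung genes (0.894), 5.39% for endothelial genes (0.814), 3.55% for pluripotency and germ cell genes (0.311), 3.09% for blood and microglia genes (0.262), 2.63% for liver genes (0.187) and 1.17% for epidermal genes (0.0710), each an adjusted p. Single members stood high: Bcl11b, a gene of cortical and other neurons, had 46.0%, Tcf15, a gene of the somites, 27.4%, the muscle filament gene Des 24.4%, the cartilage collagen gene Col2a1 24.3%, Tnnt3 23.6%, and Myod1, a regulator of muscle fate, 17.2% (14.8% ± 3.20). Windows also hold neighbouring genes, so their coverage need not belong to the named gene. Tnnt3 had no replicated peak within 5 kb of its own 5′ end. The window of Tcf15 overlapped a long stretch over the starts of Scrt2 and Srxn1. Egfl7, an endothelial gene whose window overlaps that of Notch1, had 22.3%, the endothelial receptor gene Eng 22.1%, the crest genes Prph and Tfap2a 19.9% and 19.8%, Ntrk1 19.1%, the epidermal gene Grhl3 20.5%, Apoa2 20.0%, Cdx1 19.4%, Esrrb 19.2%, Cd68 18.9% and Klf1 17.8%. Low members included Alb, the liver albumin gene, at 0.840%, Gata1, an X-linked blood gene, at 0.709%, Mitf at 1.71%, Nkx2-1 at 1.64%, Actn2 at 1.27% and Myh8 at 0.756%. The windows of Cps1, Lum, Sftpa1, Slco1a4, Hbb-bs, Dppa4, Dsg1a and Olfr1 held no replicated peak.

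Start-site occupancy was tested next. All 20 neural progenitor genes, all 30 dorsoventral patterning genes (adjusted p = 0.000151, Fisher's exact test), all 40 spinal neuron genes (8.58e-06), all 14 proneural genes (0.0272), all 22 forebrain and midbrain genes (0.00212) and all 20 housekeeping genes (0.00267, as for the progenitor list) had a replicated peak within 5 kb of the 5′ end. So did 38 of 39 Hox genes (Fisher's exact test, adjusted p = 0.000151) and 17 of 18 sclerotome genes (0.0339). Neighbouring Hox genes are not independent in this test either. The proneural list did not pass with the pooled list or without the 3 Ebf genes (11 of 11, Fisher's exact test, adjusted p = 0.0687), the forebrain and midbrain list did not pass at a fold of at least 4, and the sclerotome list did not pass under these 2 settings or with either replicate alone. Occupancy was lower for liver genes (5 of 18, Fisher's exact test, adjusted p = 0.00103), blood and microglia genes (7 of 18, 0.0151), pluripotency and germ cell genes (7 of 18, 0.0151) and olfactory receptor genes (12 of 1092, or 1.10%, against 73.8% of other genes). The blood and microglia list did not pass at a fold of at least 4. The remaining 8 lists did not pass: pan-neuronal (19 of 21), glial (15 of 18), crest (16 of 18), muscle (13 of 16), endothelial (12 of 16), heart (14 of 18), gut and lung (12 of 18) and epidermal (8 of 16) genes.

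The balance of coverage between the replicates was compared next, as a check for lists that differ between the dissections. Over all protein-coding genes, replicate 1 covered more than replicate 2, with a log2 ratio of 0.29. For 18 of the 20 lists the ratio did not pass the test against random lists, including muscle (0.05 above all genes), endothelial (0.07), blood (0.03) and crest genes (0.10). The Hox list had a log2 difference of −0.17 (permutation test, adjusted p = 0.0020), but it did not pass in 10 kb windows. Its median coverage was 52.5% in replicate 1 and 50.2% in replicate 2. Whether such dense coverage lowers the ratio was not tested. Olfactory receptor genes differed by 0.04 (permutation test, adjusted p = 0.0020), and by −0.02 with the 50000 strongest peaks per replicate, where 0 lists passed. In 10 kb windows the heart list (0.29) and the crest list (0.25) also passed. This compares 2 libraries and not conditions.

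The longest marked stretches were sought next. Joining replicated peaks across 3 kb gave 68085 stretches, and the 500 longest each had at least 15991 bases in peaks. The longest, on chromosome 8 at 120317024 to 120478360, lay in introns of Gse1 with 127449 bases in peaks. The next lay in introns of Msi2, which encodes the RNA-binding protein Musashi 2 (chromosome 11, 88533697 to 88671942), over Ssbp3 including its start (chromosome 4, 106907373 to 107026927), and again in Msi2, nearest to the start of Ccdc182 (chromosome 11, 88394019 to 88530283). They were followed by a stretch over the HoxC cluster that includes the starts of Hoxc4 to Hoxc10 (chromosome 15, 102960038 to 103076944), 1 in Gse1 nearest to the start of Gins2, and stretches in Ebf3 (chromosome 7, 137236580 to 137323623), Pknox2, Zfp608 and the chromatin remodeller gene Arid1b. Of the 812 protein-coding genes within 50 kb of the 500 stretches, 38 were Hox genes (Fisher's exact test, adjusted p = 1.84e-52) and 5 of 14 were proneural genes, namely Ebf1, Ebf2, Ebf3, Neurod2 and Nhlh1 (adjusted p = 0.000725). Notch1, Notch2 and Pax6 were the 3 of 20 progenitor genes near a stretch (Fisher's exact test, adjusted p = 0.185). Olfactory receptor genes were rarer than other genes, with Olfr221 and Olfr370 the 2 of 1092 (Fisher's exact test, adjusted p = 4.91e-15). Neighbouring Hox genes can lie near the same stretch, and olfactory receptor genes share windows too, so the p-values of these lists do not rest on independent genes. Of the 2 lists that were more frequent near stretches, the proneural list did not pass with replicate 1's list alone, the pooled list, a wider joining gap or the 200 longest stretches, nor without the 3 Ebf genes (2 of 11 genes, Fisher's exact test, adjusted p = 0.245). At a fold of at least 4 the progenitor list passed in its place.

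Several transcription factor motifs were more frequent in distal peaks, those with summits more than 2.5 kb from annotated 5′ ends, than beside them. Of 111362 distal replicated peaks, 76197 could be matched to control windows of the same GC content. Of the 20 motifs, 14 were more frequent in peaks than in controls under Fisher's exact test, with a ratio above 1 also relative to letter shuffles. Of these, 6 exceeded every shuffle, of which there were 13 for the homeodomain motif, 11 for the CTCF core and 20 for the others: the homeodomain motif TAATTA, in 18.7% of peak windows and 11.4% of control windows (ratio over shuffles 1.45; replicates 1.38 ± 0.00411), the E-box CAGCTG bound by basic helix-loop-helix factors (30.4% and 21.3%; 1.44; 1.35 ± 0.00470), the ZIC motif (18.1% and 12.9%; 1.26; 1.24 ± 0.0117), the RFX motif (6.54% and 5.06%; 1.26; 1.22 ± 0.00411), the CTCF core (6.95% and 5.06%; 1.13; 1.12 ± 0.0216) and the TEAD motif (27.2% and 25.1%; 1.12; 1.11 ± 0.00420).

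The POU motif had the highest ratio over shuffles, 1.53 (11.2% and 7.61%, replicates 1.42 ± 0.0544), though its raw ratio of 1.47 lay below the 1.64 of the homeodomain motif. Of the 20 POU shuffles, 1 was as high. The HNF1 motif (1.27), the forkhead motif (1.21), the NFI site (1.19), the MEIS/PBX motif (1.16), the E-box CAGATG (1.11), the SOX motif (1.05) and the GATA motif (1.022) likewise had 1 to 9 shuffles as high. Motifs of OTX and PITX factors (0.893), GLI factors (0.941) and nuclear receptors (0.998) were less frequent in peaks than in controls, but 17, 13 and 10 of their 20 shuffles were as high, so they lay within the range of the shuffles; the nuclear receptor ratio was 1.01 in each replicate's own list. For AP-1, CREB and ETS the raw ratio (0.949, 1.10 and 1.11) and the ratio over shuffles (1.04, 0.955 and 0.841) pointed in opposite directions, so these were not called. The tests count windows and not samples, and short motifs do not identify which factor binds.

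**Figure D4:**
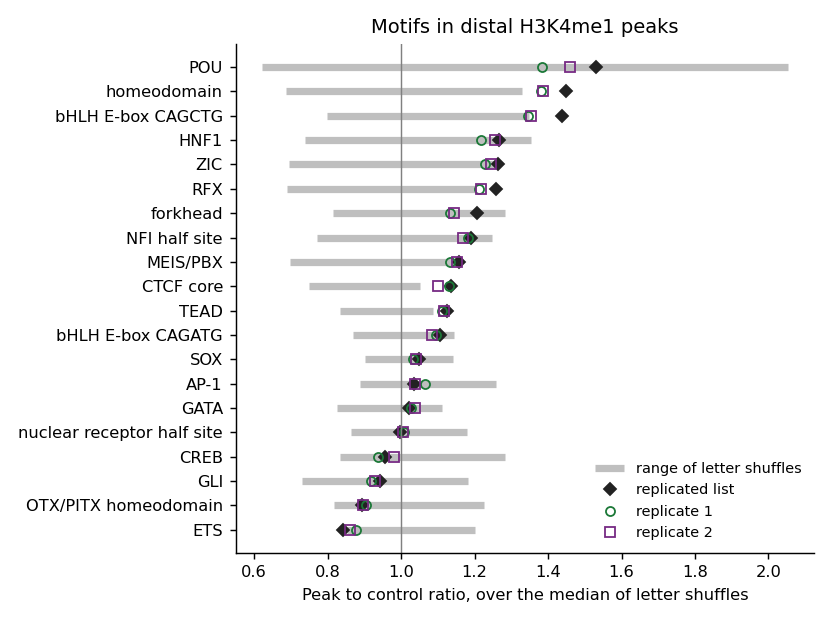
Ratio of distal peak windows to control windows holding each motif, divided by the median ratio of the motif's letter shuffles (x axis), per motif (y axis). Diamonds, circles and squares are the replicated list, replicate 1 and replicate 2, and grey bars span the shuffles; the homeodomain and CAGCTG diamonds, at 1.45 and 1.44, lie beyond their shuffles, while the POU diamond at 1.53 lies within them.

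Chromosome X carried few peaks. It held 6.99 replicated peaks per Mb of sequenced bases, while autosomes ranged from 45.9 on chromosome 14 to 85.5 on chromosome 11. Replicated peaks covered 0.512% of X, against 4.01% of chromosome 3, the lowest autosome, and 9.18% of chromosome 11. Of the 948 protein-coding 5′ ends on X, 38.2% (95% interval 35.1 to 41.4) had a replicated peak within 5 kb, against 58.2% or more on every autosome. Of the 11 X-linked members of the lists other than that of olfactory receptor genes, 9 lay below the median of all genes, among them Sox3, Plp1, Hprt and Gata1, and 2 lay above it, the neuronal genes Dcx (12.3%) and L1cam (8.68%), named here after their values were seen.

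**Figure D5:**
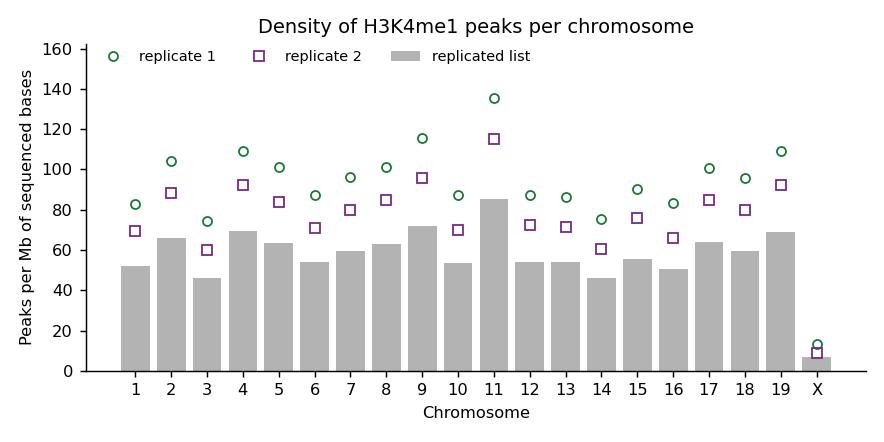
Replicated peaks per Mb of sequenced bases (y axis, bars) for each chromosome (x axis), with the density in each replicate's own list as circles and squares. Chromosome X stands at 6.99 per Mb in the replicated list and the autosomes between 45.9 and 85.5.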

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

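Peaks outside the assembled chromosomes entered no comparison. The pooled list held 6 peaks on an unplaced contig assigned to chromosome X, more than the limit of 3 that a count of 0 allows, and was picked out for that reason. Each replicate's own list held 3 peaks on this contig and the replicated list 1. The highest fold enrichment there was 2.78 in the pooled list and the longest peak spanned 520 bp. No explanation was tested for these few peaks.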

How the results depend on the processing

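The gene list run on autosomal genes only, the proneural list without its Ebf genes and the motif call against every shuffle were chosen after seeing the data. With autosomal genes only, 8 lists again lay above random lists and 1 below. Over all alternatives, 98 results gave 632 values. Of these, 513 kept their direction and side of the threshold or, with no test, stayed within a range around the main value. A further 16 no longer passed, 5 newly passed, 61 moved further and 37 changed direction. The range differed between results. It was the spread of the replicates for positions relative to genes. For shared, replicate-specific and kept pooled peaks and the rank correlation, it was the confidence interval of the main value. The call of each of the 20 motifs was kept under the other peak lists, minimums and windows tried. The cause was not tested where a value changed below, except where fewer peaks or another definition changes it by construction. The shared shares of replicates 1 and 2 and their rank correlation were 61.7%, 79.8% and 0.467 with a −log10 q of at least 5, 55.4%, 76.7% and 0.485 with a fold of at least 4, 62.3%, 81.3% and 0.497 with an overlap of 1 bp, 37.8%, 45.6% and 0.621 with 50% of both peaks, 69.2%, 73.8% and 0.429 with the 50000 strongest peaks each, and 61.2%, 76.6% and 0.630 after joining across 500 bp. The shares of replicate-specific peaks were 36.1% and 18.1%, 43.5% and 22.3%, and 29.7% and 25.1% under the q, fold and 50000 settings. Pooled peaks were kept at 89.8% and 99.97% under the q and fold settings. The promoter ratio was 3.23 and 4.32 under these, 2.22 with the pooled list, 2.37 with promoters of 2.5 kb, 5.05 with protein-coding genes, and 2.44 to 2.69 with 1 replicate left out. The ratio of start sites to flanks was 0.468 at a fold of at least 4 and 0.577 to 0.650 with 1 replicate left out. At a fold of at least 4, which leaves fewer peaks, 5 lists lay above random lists, and the spinal neuron, pan-neuronal and glial lists, higher by 2.09, 3.03 and 2.65 percentage points, did not pass. With 1 replicate left out, the spinal neuron list was higher by 2.94 to 3.37 points and the glial list by 4.817 to 5.002, and neither passed without replicate 2. Against lists of like gene density the housekeeping list was higher by 5.29 points and did not pass. Lists that passed only under an alternative were forebrain and midbrain genes, higher by 6.73 points over gene bodies, sclerotome genes, higher by 11.7 points in 10 kb windows, and epidermal genes, at −6.43 points with the pooled list, which made 2 lists below random. With the 50000 strongest peaks, 0 lists differed in balance, and that of olfactory receptor genes turned to −0.0193 on the log2 scale. The number of lists enriched near long stretches was 1 with the pooled list, a wider joining gap, the 200 longest stretches or without the Ebf genes, and 1 to 2 with 1 replicate left out; the proneural list was the one lost. It again numbered 2 at a fold of at least 4, with the progenitor list in place of the proneural list. Without its Ebf genes the proneural list no longer passed in start-site occupancy. Of 14 motifs, 6 passed when the ratio also had to exceed every letter shuffle. Of the values that changed direction, the olfactory receptor balance above was the only one called in either setting; the others were not called in both. In coverage, muscle genes turned to −0.2905 points under the q setting and −0.1045 with autosomal genes only. In log2 odds of occupancy, muscle and endothelial genes both turned to −0.08788 under the q setting and −0.4092 in 1 kb windows. At a fold of at least 4, muscle, endothelial, heart and glial genes turned to −0.6995, −0.01693, −0.6634 and −0.05314. In log2 balance, dorsoventral, proneural, liver and pluripotency genes turned to 0.04756, 0.046, 0.07877 and 0.0936 under the q setting. At a fold of at least 4, dorsoventral, proneural, liver, epidermal and sclerotome genes turned to 0.1764, 0.1134, 0.2198, 0.008335 and −0.0643. With the 50000 strongest peaks, dorsoventral, proneural, liver, epidermal, sclerotome and gut and lung genes turned to 0.1298, 0.09141, 0.1735, 0.01674, −0.1305 and −0.06992, and in 10 kb windows proneural, pluripotency, gut and lung and housekeeping genes to 0.001642, 0.04265, −0.1062 and −0.06041. The nuclear receptor ratio turned to 1.006 to 1.007 with 1 replicate left out, 1.012 with the pooled list, 1.010 with controls 10 kb away and 1.041 in 200 bp windows, and at a fold of at least 4 AP-1 turned to 0.9909 and CREB to 1.025. Without read depth, the lower limit of detection is unknown, and a gene without a peak is one without a call at the authors' threshold.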

Other observations

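The tests of gene content on chromosome X, of dorsal against ventral genes and of the order of Hox genes were chosen after results were seen, the last after coverage in wider windows around these genes. Within the Hox clusters coverage differed between genes. In the 10 kb around the 5′ end, Hoxa2, Hoxa4 and Hoxa5 had 97.46%, 95.8% and 97.2% of bases in replicated peaks, and Hoxa13 12.8%. Hoxc8 had 89.3%, Hoxc10 38.8%, Hoxc11 0% and Hoxc13 15.1%, and Hoxd10 25.6% and Hoxd12 9.99%. The rank correlation of paralog number and this coverage was −0.5 or lower in 3 of the 4 clusters, at −0.855 in HoxA, −0.75 in HoxC and −0.717 in HoxD, and −0.316 in HoxB. The outermost annotated 5′ end of some genes lies beside another Hox gene, that of Hoxc5 46639 bp from its start codon. Around the most frequent start codon, Hoxc5 had 97.4%, Hoxa3 97.2%, Hoxd3 94.2% and Hoxd4 98.2%, and the correlations were −0.873 in HoxA, −0.285 in HoxB, −0.879 in HoxC and −0.683 in HoxD. Hoxd1, at 25.1%, and Hoxb1, at 30.4%, were low at the anterior end. As the windows lie within those from which the pattern was read, these values describe a fall from anterior to posterior genes and do not test it independently.

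In the genes of dorsoventral patterning, grouped after their values were seen, the median coverage was 17.2% for 11 dorsal genes (Pax3, Pax7, Msx1, Msx2, Msx3, Lmx1a, Gdf7, Wnt1, Wnt3a, Bmp7, Gli3) and 8.35% for 11 ventral genes (Shh, Foxa2, Arx, Nkx2-2, Nkx2-9, Nkx6-1, Nkx6-2, Olig1, Olig2, Ptch1, Gli1). The medians differed by 5.48 and 6.26 percentage points in replicates 1 and 2. The lowest dorsal gene was Lmx1a at 7.38%, and Ptch1 at 34.8% was the highest ventral gene. A two-sided permutation test gave p = 0.0119 with 100000 resamples, but it cannot support a difference read from the same values, so whether dorsal and ventral genes differ stays open.

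Chromosome X had few peaks, and 3 technical explanations were weighed. A lower number of genes was argued against. X held 5.80 coding genes and 6.99 replicated peaks per Mb. Chromosomes 12 and 18, with 5.50 and 5.83 coding genes per Mb, held 53.9 and 59.7 replicated peaks per Mb. Of X-linked coding starts, 38.19% had a peak nearby, and the lowest autosome had 58.2%. A higher repeat-masked share was argued against as the whole cause. In 1 Mb bins of like masked share, X had 0.3496 of the autosomal number of peaks (95% bootstrap interval 0.290 to 0.412, 149 bins). Without matching the ratio was 0.130, so part of the deficit went with repeat share. The masked share does not measure where reads can be placed, so the matching cannot decide whether more reads on X were unplaceable. Lower read coverage of X cannot be told apart: at matched fold and length the −log10 p of X peaks was 0.9936 of that of autosomal peaks, but a background set genome-wide by the caller would lower fold as well and leave this ratio at 1, and the caller is not given in the sources used here. The X to autosome ratio of pooled peak density fell from 0.141 with no minimum to 0.0577 at a fold of 4 and 0.0113 at a fold of 6; the 1 tissue of pooled sexes allows no test of a biological explanation such as the silencing of an X copy in females.

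Coverage was higher downstream than upstream of coding starts, and 2 technical explanations were weighed. Over all protein-coding genes, 38.7% of bases 1 to 2 kb downstream and 15.7% upstream lay in replicated peaks, a ratio of 2.47. Further annotated starts downstream were argued against as the whole cause, since the ratio was 2.187 (95% bootstrap interval 2.08 to 2.32) in 6848 genes whose transcripts all start within 100 bp. In the 2486 of these genes with 2 or more annotated transcripts, the ratio was 2.447 (2.25 to 2.67). GC content was argued against as the whole cause too, since the ratio was 1.942 (1.88 to 2.01) in 9435 genes with at least as much GC upstream, although it was lower than over all genes, and 1.64 (1.52 to 1.79) in the 3017 genes that met both conditions. With 1 group no biological explanation was tested.

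Replicate 1 had more peaks without a counterpart than replicate 2. Calls placed at random along the chromosomes are argued against: of 65748 such peaks outside replicated peaks, 71.47% lay within 5 kb of a replicated peak, against at most 29.0% in 100 circular shifts. The shifts cannot exclude false calls that gather near replicated peaks, since these would give a high share too. A laxer effective threshold in replicate 1 stays open: with its strongest 191032 peaks, as many as replicate 2 had, the gap in unmatched shares was 7.708 percentage points, down from 19.0, between the bounds of 5 and 10 points set in advance. No biological explanation was tested, since the replicates belong to 1 group.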
